A study of Mus musculus with 12 samples.

How the data were processed

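Poly(A) RNA from the mouse macrophage line RAW264.7 was sequenced in 12 libraries. Per the labels, 4 libraries came from untreated control cells. Another 4 came from cells given lipopolysaccharide (LPS, the bacterial outer membrane component sensed by Toll-like receptor 4) at 1 µg/mL for 24 h. The remaining 4 came from cells given ferulic acid, a plant phenolic acid, at 10 µM for 12 h and then the same LPS treatment. The labels do not say whether the 4 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical only.

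Whole-number read counts per gene were deposited for each library, per the file headers, and these counts carry no normalization. The FPKM values beside them were deposited too, per the file headers, and each one is proportional to the count divided by the gene length and by the library's total count in the table. That relation was tested on the table itself and gives 1 whole-number length per gene. Per the submitters' processing notes, the tools were fastp 0.23.4, HISAT2 2.2.1, featureCounts 2.0.6, DESeq2 1.34.0 and edgeR 3.36.0 with the mouse genome build GRCm39. Which of these made the deposited counts, in what order, with which annotation release and with which strand setting is not given in the sources used here. Per the labels' protocols, mRNA was selected with oligo-dT beads, so transcripts without a poly(A) tail, such as most replication-dependent histone mRNAs, are measured incompletely. Reads of near-identical copies (ribosomal protein genes and Gapdh with their pseudogenes, the Bcl2a1 genes, the H2-Q genes, the clustered histones, the Gbp genes) could be lost or shared in the authors' counting, and those genes are uncertain. Without the strand setting, reads of overlapping antisense genes cannot be told apart. No genome coordinates are given, because the annotation used here is of an earlier build, and it served only for transcript GC content.

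The table holds 25192 genes, each with at least 1 read in some library. Of these, 91 have no symbol and 18 repeat a symbol, and they were kept under their identifiers. Totals ran from 32548423 to 49961581 counts per library. Intervals on counts and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Comparison of all pairs of libraries within a group gave a chi-square per gene of at least 12.8, so no pair agreed within sampling noise and each library counts as 1 replicate.

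The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts, with TMM scaling, group as the only term, all 12 libraries in one fit and the filter of filterByExpr. The filter kept 14065 genes and left out 11127, which hold 0.0421% of all reads. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p of a gene below is from this test unless another tool is named. The 3 comparisons were LPS against control, ferulic acid plus LPS against LPS, and ferulic acid plus LPS against control. Standard errors (SE) are the log2 fold change divided by the square root of F, and intervals are 95%. CPM values are counts scaled to the TMM-adjusted library size.

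Altogether 37 gene lists were fixed for the tissue and the treatment. They cover proinflammatory cytokines, chemokines, NF-kB targets, interferon-stimulated genes, guanylate-binding and immunity-related GTPases, TLR4 signalling, other pattern receptors, nitric oxide and prostaglandin enzymes, the peroxiredoxin and thioredoxin system, NRF2 targets, NADPH oxidase and redox enzymes, inflammasome, feedback inhibitors, alternative activation, MHC class I and II, glycolysis, oxidative phosphorylation, cholesterol synthesis and efflux, cell cycle, p53 targets, stress responses, lysosome, proteases and complement, macrophage identity, markers of 7 other cell types and 3 lists for RNA quality. The 35 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 on log2 CPM, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. Some members belong to more than 1 list or are expressed by macrophages as a rule, such as Itgax among the dendritic cell markers.

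Groups, tests, lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule names, per comparison, up to 8 called genes with the largest rise and up to 8 with the largest fall among those with a mean log2 CPM of at least 3 and no overlap between the 4 libraries of one group and the 4 of the other. It adds 13 readout genes whatever their result, and for each list described the members with the largest change among those that pass, or the smallest p if none passes. That last number was set to 2 per list, and the lists to describe were picked, after the list results had been seen. The results of the other lists are given as counts. The results of 1 gene that the rule would add are not reported here, though it stays in the tests and list counts.

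The alternative settings were RLE scaling, library size scaling, DESeq2 1.42.0, no low-count filter, a filter of 10 CPM in 4 libraries, a fit of only the 2 groups compared, the replicate number as a block, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes of at least 1 FPKM in 4 libraries, a fold minimum, and each library left out in turn. Removal of a GC or length trend per library, library weights and the omission of ferulic acid plus LPS libraries 1 and 4 or 2 and 3 were added after the data had been seen.

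The tests were checked on simulated counts drawn from the real means and library sizes with known changes. For ferulic acid plus LPS against LPS, over 13571 genes, the edgeR test recovered 26.9% of genes changed 1.5-fold, 70.1% at 2-fold and 100% at 4-fold, and 5.07% of its calls were false. DESeq2 recovered 40.3% at 1.5-fold and 83.6% at 2-fold there, with 15.3% false calls. On the simulated data without change camera called 0 of 35 lists, and with 1 list raised by a log2 of 0.50 it called that list alone. Genes were drawn independently in all simulations, without correlation between genes, a GC trend or other structure among libraries. The simulated rates of false calls therefore do not cover errors from such structure in the real data.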

Results

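The transcriptome of RAW264.7 cells, a mouse macrophage-like line, was measured in 4 control, 4 LPS and 4 ferulic acid plus LPS libraries. The series title names ferulic acid, macrophage activation through the receptor TLR4, and peroxiredoxin 1. Total counts per library ran from 34261236 to 48446195 in control, from 35866432 to 47276784 in LPS and from 32548423 to 49961581 in ferulic acid plus LPS libraries. The first principal component of log2 CPM held 77.8% of the variance and set the control libraries apart from the 8 LPS-treated ones. The second held 6.81%, and the LPS libraries scored 12.5 to 41.3 on it. Ferulic acid plus LPS library 2 (score 25.6) lay within that range and library 3 (7.56) just below it. Libraries 1 (score -44.0) and 4 (score -76.6) of the ferulic acid plus LPS group stood apart from both. Within that group, libraries 1 and 4 were the closest pair (chi-square per gene of 29.4) and library 2 was the farthest from both (337 and 448), and voom quality weights were lowest for libraries 2 (0.195) and 3 (0.345), against 1.63 and 0.600 for 1 and 4. Which of these pairs departs from the group thus depended on the measure. The 50 most abundant genes took 20.8% ± 0.432 of the reads in control, 33.8% ± 1.68 in LPS and 34.1% ± 2.65 in ferulic acid plus LPS libraries. Ribosomal protein genes took 9.40% ± 1.10, 16.4% ± 1.01 and 19.1% ± 4.04 in the same order, with 22.3% in library 1, 14.1% in library 2, 17.7% in library 3 and 22.5% in library 4 of the last group.

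**Figure D1:**
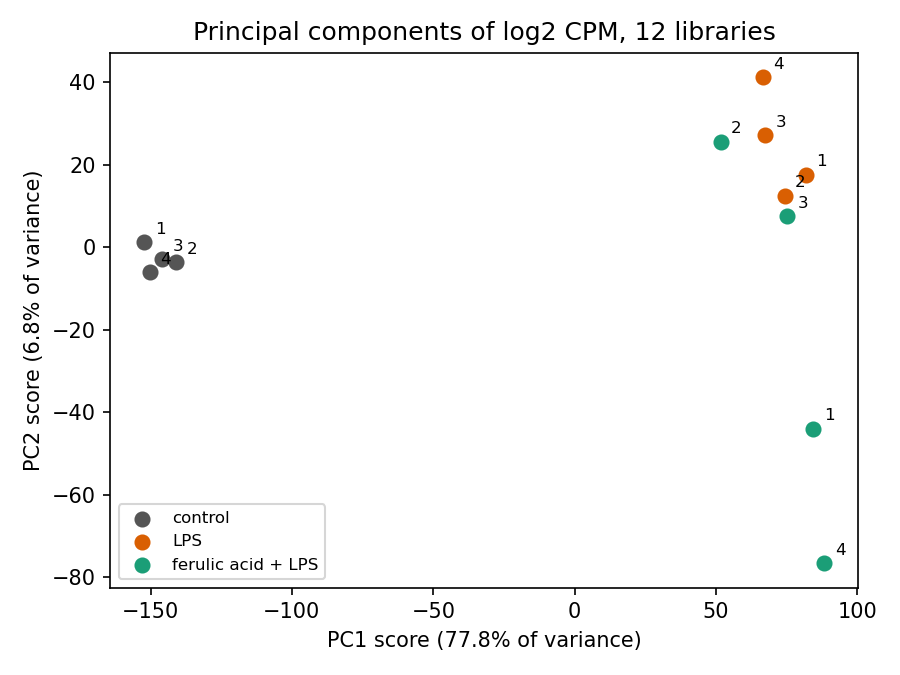
Scores of the 12 libraries on the first 2 principal components of log2 CPM, 1 point per library with its replicate number, coloured by group. The control libraries lie between -152 and -141 on the first component, and ferulic acid plus LPS libraries 1 and 4 lie lowest on the second, at -44.0 and -76.6.

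The comparison of LPS with control asked how 24 h of LPS changed the cells. Of 17 proinflammatory cytokines 16 rose (camera adjusted p = 2.1e-09, and adjusted p = 0.0122 with an estimated correlation). Csf3, which encodes the granulocyte growth factor G-CSF, went from 0.0512 ± 0.0495 CPM to 6291 ± 707 CPM (SD, n = 4 each), a log2 fold change of 16.74 (SE 0.45, adjusted p = 2.0e-14). Ptgs2, the inducible cyclooxygenase, rose from 2.54 ± 0.303 to 7167 ± 1099 CPM (log2 fold change 11.46, SE 0.32, adjusted p = 2.1e-14). Of 26 G2 and mitosis genes 23 fell, and of 23 cholesterol synthesis genes 16 fell, both lists with camera adjusted p = 0.104 with an estimated correlation. Tlr4, the LPS receptor itself, fell from 29.8 ± 3.00 to 3.81 ± 0.955 CPM (log2 fold change -2.97, SE 0.29, adjusted p = 9.3e-08). Prdx1, which encodes peroxiredoxin 1, rose from 685 ± 111 to 4004 ± 420 CPM (log2 fold change 2.55, SE 0.28, adjusted p = 4.9e-07).

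Of the 14065 genes tested, 10384 changed in this comparison, 5003 higher and 5381 lower, and 7372 of them by at least 2-fold (3445 higher, 3927 lower). In 75.3% of the genes the 4 LPS and 4 control libraries did not overlap, against 2.86% by chance. With library size scaling the split was 2467 higher and 8305 lower, and with limma on log2(FPKM + 1) it was 2200 higher and 6768 lower. The median log2 fold change of all genes was -0.10 with TMM and -0.99 with library size scaling, so small changes below are relative to the TMM baseline.

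Among genes with a mean log2 CPM of at least 3 and no overlap between the groups, the other largest rises were those of Lcn2 (log2 fold change 15.31, SE 0.42), an iron-sequestering secreted protein, the interleukins Il1b (13.68, SE 0.43) and Il1a (13.31, SE 0.41), Urah (13.51, SE 0.30), an enzyme of urate breakdown, and the chemokine Cxcl2 (12.43, SE 0.28). Urah and Il1a had 4 and 6 reads over the 4 control libraries, so their folds are less certain than the SE shows. Il6 and Csf2 had only 2 reads each there. Their pooled reads rose 112575-fold (95% counting interval 31164 to 929568) and 24779-fold (6859 to 204605). By the same rule the largest falls were those of Kbtbd11 (-6.76, SE 0.31), the sialic acid receptor Cd33 (-4.98, SE 0.20), the integrin chain Itga4 (-4.95, SE 0.19), the fatty acid oxidation enzyme Cpt1a (-4.82, SE 0.35), the phagocyte receptor Trem2 (-4.71, SE 0.19), the S-adenosylmethionine synthase Mat2a (-4.68, SE 0.19), the sulfate transporter Slc26a2 (-4.60, SE 0.21) and Stard9 (-4.47, SE 0.25). Adjusted p was at most 2.6e-09 for each of these. Among the readout genes, Tnf rose from 13.5 ± 2.59 to 501 ± 93.8 CPM (log2 fold change 5.21, SE 0.20), Nos2, the inducible nitric oxide synthase, from 12.5 ± 0.984 to 315 ± 39.2 CPM (4.66, SE 0.21), and Hmox1, haem oxygenase 1, from 113 ± 6.27 to 709 ± 150 CPM (2.65, SE 0.20). The chemokines Ccl2 (9.18, SE 0.39) and Cxcl10 (6.70, SE 0.21) rose as well. Il10, an anti-inflammatory cytokine, had 2 control reads and 197 LPS reads, a ratio of 176 (counting interval 48.6 to 1451). Nlrp3, the inflammasome sensor, fell (-0.91, SE 0.22, adjusted p = 0.00122). Arg1 had 48 reads over all 12 libraries and was not tested.

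**Figure D2:**
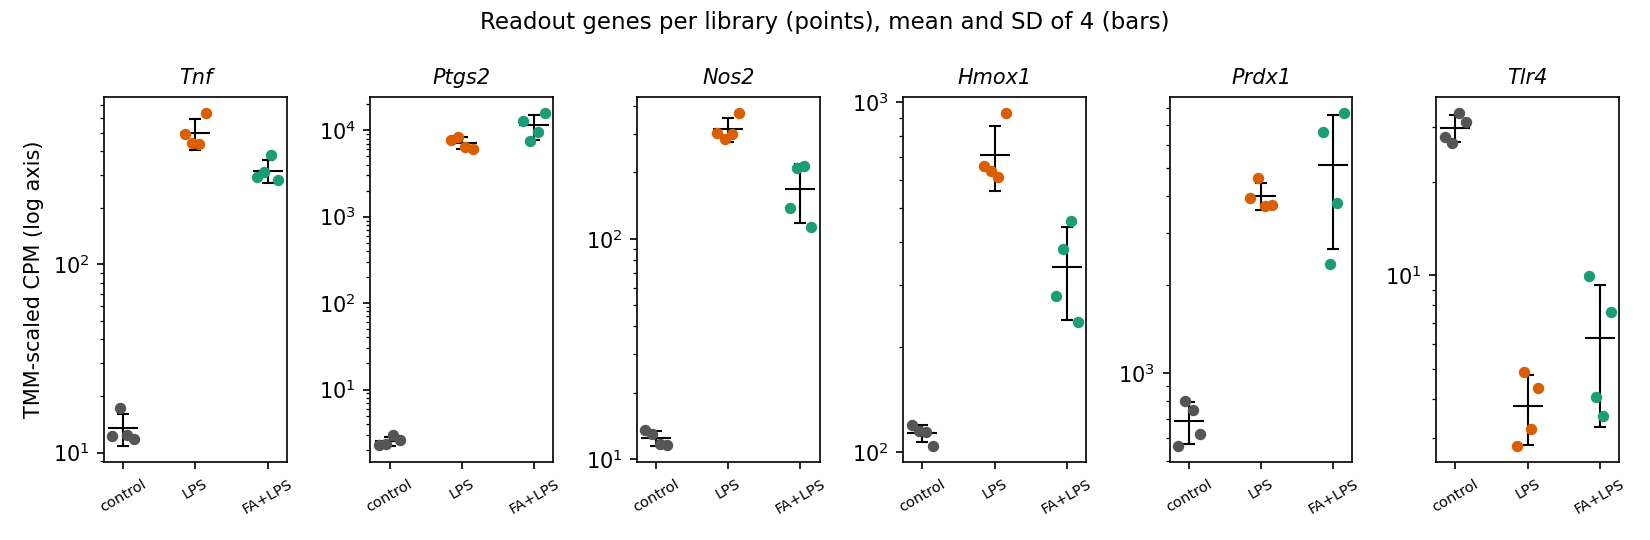
TMM-scaled CPM on a log axis of 6 readout genes in each of the 12 libraries (points), with the mean and SD of the 4 libraries of a group (bars). Tnf averages 13.5 CPM in control, 501 CPM in LPS and 315 CPM in ferulic acid plus LPS libraries.

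With an estimated correlation 5 lists kept their call. Of the 17 proinflammatory cytokines, 16 rose and 1 did not pass, over all genes and also adjusted over the list alone (camera adjusted p = 2.1e-09, and adjusted p = 0.0122 with an estimated correlation), led by Csf3 and Il6. Among 20 NF-kB targets, 18 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 1.8e-07, and adjusted p = 0.0122 with an estimated correlation), with the costimulatory receptor Cd40 at 6.73 (SE 0.20) and the NF-kB cofactor Bcl3 at 6.26 (SE 0.20). Of the nitric oxide, itaconate and prostaglandin enzymes, 11 of 14 rose and 3 fell, likewise adjusted over the list alone (camera adjusted p = 0.00110, and adjusted p = 0.0423 with an estimated correlation), led by Ptgs2 and the itaconate enzyme Acod1 (7.07, SE 0.17). Of the protease, coagulation and complement genes, 12 of 16 rose and 3 fell, and 12 and 4 did adjusted over the list alone (camera adjusted p = 0.00253, and adjusted p = 0.0423 with an estimated correlation). The collagenase Mmp13 had 2 control reads against 13842 (ratio 12347, counting interval 3418 to 101956), and the protease inhibitor Timp1 rose by 9.71 (SE 0.30). Of the p53 and apoptosis genes, 16 of 22 rose and 4 fell, likewise adjusted over the list alone (camera adjusted p = 0.00253, and adjusted p = 0.0423 with an estimated correlation). Its leading members were the kinase Plk2 (7.66, SE 0.24) and the survival gene Bcl2a1a (7.57, SE 0.42), 1 of several near-identical copies.

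Other lists passed camera at the preset correlation and lost the call with an estimated one. Of 13 chemokines, 12 rose (adjusted p = 1.0e-07, and adjusted p = 0.0633 with an estimated correlation), with Cxcl2 and Ccl5 (11.86, SE 0.34) leading. Of 35 interferon-stimulated genes, 29 rose and 4 fell (adjusted p = 1.8e-07, and adjusted p = 0.0667 with an estimated correlation). The nucleic acid sensor Zbp1 rose by 7.96 (SE 0.27), and the interferon gene Ifnb1 had 2 control and 365 LPS reads (ratio 326, counting interval 90.1 to 2688). Of 20 feedback inhibitors of TLR signalling, 18 rose and 2 fell (adjusted p = 2.1e-07, and adjusted p = 0.0633 with an estimated correlation). Il1rn, the interleukin-1 receptor antagonist, rose by 8.19 (SE 0.20). In these 3 lists the counts adjusted over the list alone were the same. Of 17 MHC class I and antigen processing genes, 14 rose and 2 fell, with 15 and 2 adjusted over the list alone (adjusted p = 2.0e-04, and adjusted p = 0.180 with an estimated correlation). The peptide transporter Tap1 rose by 2.78 (SE 0.15) and H2-Q6, a member of a multicopy family, by 2.59 (SE 0.40). Of 22 unfolded protein and integrated stress response genes, 17 rose and 4 fell, also adjusted over the list alone (adjusted p = 3.7e-04, and adjusted p = 0.123 with an estimated correlation), led by the transcription factor Ddit3 (4.43, SE 0.18) and the chaperone Hspa5 (3.39, SE 0.16).

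Of 17 peroxiredoxin and thioredoxin genes, 12 rose and 3 fell, with 13 and 3 adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.176 with an estimated correlation). The list median was 0.79 with TMM and -0.10 with library size scaling, where the call was lost (adjusted p = 0.0882, in a range of 4.6e-08 to 0.176 over 22 alternatives). Prdx5 rose by 5.19 (SE 0.22) and the glutaredoxin Glrx by 3.56 (SE 0.16), and Prdx1 rose under both scalings. All 28 ribosomal protein genes tested rose, over all genes and adjusted over the list alone, with a median of 1.58 with TMM and 0.68 with library size scaling (camera adjusted p = 6.5e-08, and adjusted p = 0.255 with an estimated correlation), Rps20 by 2.76 (SE 0.31) and Rplp1 by 2.60 (SE 0.29). Across genes, which are not independent replicates, the LPS fold change fell with gene length (Spearman rho = -0.349), and the slope of log2 CPM on length relative to the LPS mean was 0.44 ± 0.04 per doubling in control and -0.02 ± 0.08 in ferulic acid plus LPS libraries (SD, n = 4 each). With the length trend removed the ribosomal protein median was 1.26 (camera adjusted p = 1.3e-06). The 19 macrophage identity genes did not move as a list (10 higher, 7 lower, camera adjusted p = 0.538), and its median flipped from 0.53 with TMM to -0.37 with library size scaling. The Fc receptor Fcgr3 fell (-4.05, SE 0.31) and so did the fractalkine receptor Cx3cr1 (-3.25, SE 0.20).

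Of 26 G2 and mitosis genes, 23 fell and 1 rose (camera adjusted p = 9.7e-07, and adjusted p = 0.104 with an estimated correlation), with the kinetochore gene Cenpf at -4.13 (SE 0.22) and the proliferation marker Mki67 at -3.60 (SE 0.17). Of 28 S phase genes, 17 fell and 4 rose (camera adjusted p = 0.0336, and adjusted p = 0.144 with an estimated correlation), among them the polymerase gene Pole (-2.78, SE 0.20) and the ribonucleotide reductase gene Rrm1 (-2.00, SE 0.17). This call was lost without control library 2 (adjusted p = 0.0513) or LPS library 4 (adjusted p = 0.0553), in a range of 7.5e-08 to 0.144 over 22 alternatives. Of 23 cholesterol synthesis genes, 16 fell and 2 rose (camera adjusted p = 0.00140, and adjusted p = 0.104 with an estimated correlation), Hmgcs1 by a log2 fold change of -3.35 (SE 0.20). The counts of these 3 lists were the same when adjusted over the list alone. The 35 TLR4 signalling genes went both ways, 11 higher and 17 lower, likewise adjusted over the list alone (camera adjusted p = 0.637), with Tlr4 and the adaptor Tab3 (-2.38, SE 0.33) lowest. Across lists, camera called 17 of 35 (14 higher, 3 lower), and 5 with an estimated correlation. Each named gene kept its call in every alternative run for it.

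The comparison of ferulic acid plus LPS with LPS asked what ferulic acid pretreatment changed in LPS-treated cells. Differences were small beside the LPS response and 40 genes changed, 12 higher and 28 lower. Hmox1 fell from 709 ± 150 to 339 ± 100 CPM (log2 fold change -1.06, SE 0.19, adjusted p = 0.0476), and Nos2 fell from 315 ± 39.2 to 169 ± 50.8 CPM (-0.90, SE 0.18, adjusted p = 0.0487). Tnf was at 501 ± 93.8 CPM with LPS and 315 ± 44.6 CPM with ferulic acid plus LPS, and its change did not pass (-0.67, SE 0.16, adjusted p = 0.0797). Prdx1 was at 4004 ± 420 and 5121 ± 2464 CPM, a log2 fold change of 0.35 (95% interval -0.21 to 0.92, adjusted p = 0.437). Tlr4 stood at 3.81 ± 0.955 and 6.29 ± 3.04 CPM and did not pass either (0.71, 95% interval 0.12 to 1.30, adjusted p = 0.156).

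The smallest adjusted p was 0.0115, 16 of the 40 genes changed by at least 2-fold, 3236 genes had an unadjusted p under 0.05 against 703 by chance, and 7.02% of genes had no overlap between the groups against 2.86% by chance. The count moved widely: 1041 genes with DESeq2, 719 without the low-count filter, 71 with a filter of 10 CPM, 2 with library size scaling, 0 with edgeR on only the 2 groups (2082 at an unadjusted p under 0.05), and 5 and 3 with limma on FPKM plus 1 and plus 0.1. It was 7 without ferulic acid plus LPS libraries 1 and 4 and 5664 without libraries 2 and 3 (2685 higher, 2979 lower, all 40 among them). It was 1 without any single control library (1, 2, 3 or 4), 0, 1, 2 and 0 without LPS library 1, 2, 3 and 4 (with 2781 genes at an unadjusted p under 0.05 without library 1 and 2057 without library 4), and 1, 2670, 1415 and 5 without ferulic acid plus LPS library 1, 2, 3 and 4. In each fit without a control library all 40 genes kept their sign and an adjusted p under 0.1. The main fit estimates each gene's dispersion over all 12 libraries, so these p-values rest partly on the spread among controls. Pairs of control libraries gave a chi-square per gene of 12.8 to 46.1, against 37.4 to 87.6 in LPS and 29.4 to 448 in ferulic acid plus LPS. In the edgeR fit of only the 2 groups the smallest adjusted p was 0.173.

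Among the named genes, Sh2d3c, a signalling adaptor gene, fell the most, from 14.8 ± 3.00 to 6.38 ± 0.611 CPM (-1.21, SE 0.16, adjusted p = 0.0115). Tbc1d2 (-1.18, SE 0.24), the aminopeptidase Anpep (-1.15, SE 0.22), Wdr81 (-1.05, SE 0.16), the elongation factor Ell (-0.92, SE 0.17) and Aar2 (-0.91, SE 0.19) fell. Evi2a rose from 40.2 ± 6.36 to 91.8 ± 32.2 CPM (1.19, SE 0.21), and Heca (0.93, SE 0.18), Fam133b (0.88, SE 0.17), the ubiquitin ligase scaffold Cul1 (0.87, SE 0.17), the lamin B receptor gene Lbr (0.83, SE 0.17) and the retinoblastoma gene Rb1 (0.74, SE 0.15) rose. Adjusted p was at most 0.0497 for each. The genes that fell had a median transcript GC content of 56.0%, those that rose 43.9%, and all tested genes 50.5%. With a GC trend removed per library, 2 genes were called, Sh2d3c and the plasminogen activator gene Plau, and the 40 genes kept a median share of 0.761 of their log2 fold change. The remaining readout genes did not pass: Ptgs2 (0.67, SE 0.20, adjusted p = 0.105), Il1b (0.49, SE 0.24, adjusted p = 0.231), Il6 (0.42, SE 0.29, adjusted p = 0.390), Il10 (0.52, SE 0.56, adjusted p = 0.604), Cxcl10 (-0.16, SE 0.16, adjusted p = 0.555), Ccl2 (-0.20, SE 0.25, adjusted p = 0.650) and Nlrp3 (0.17, SE 0.22, adjusted p = 0.662). Some readouts passed in an alternative. Without ferulic acid plus LPS library 2, Prdx1, Il6, Tlr4, Ptgs2 and Tnf did, without library 3 Tlr4, Ptgs2 and Tnf did, and with DESeq2 Ptgs2 and Tnf did. Over 20 alternatives adjusted p ran from 0.0457 to 0.990 for Prdx1, from 0.0476 to 0.942 for Il6, from 0.0358 to 0.507 for Tlr4, from 0.0105 to 0.305 for Ptgs2 and from 0.00560 to 0.269 for Tnf. Hmox1 and Nos2 kept their calls in 5 of 20 alternatives each and Sh2d3c in 16. These 20 leave out several settings that were run for the gene counts only. Of the 40 genes, all stayed called with no low-count filter, with library weights and without libraries 2 and 3. In the others, 36 stayed called with the 10 CPM filter, 3 with FPKM plus 0.1 and 3 without libraries 1 and 4.

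**Figure D3:**
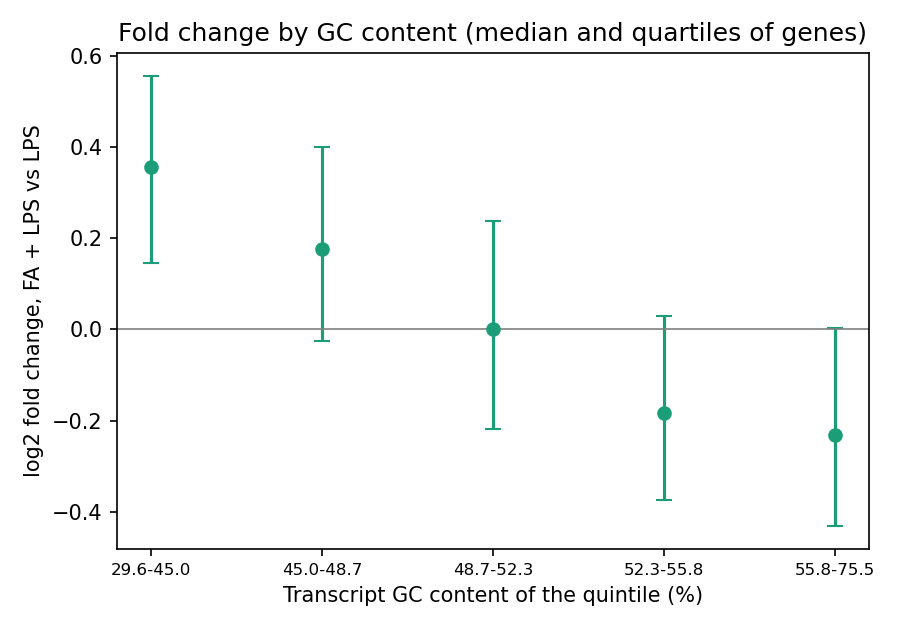
Log2 fold change of ferulic acid plus LPS against LPS in 5 bins of transcript GC content, with the median of the genes (points) and their quartiles (bars). The median falls from 0.36 in the lowest bin to -0.23 in the highest.

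Camera at the preset correlation called 7 of the 35 lists, 3 higher and 4 lower, and 0 with an estimated correlation (adjusted p of 0.270 or more), while fry called 15. No member of these 7 lists passed over all genes, so the counts that follow are adjusted over the list alone. Libraries 1 and 4 of the ferulic acid group, which lay apart from 2 and 3 on the second component and carried the highest ribosomal protein shares (22.3% and 22.5%), enter each of them, as do libraries 2 and 3 with the lowest weights. Of 9 guanylate-binding and immunity-related GTPases, which act in defence against intracellular pathogens, 5 were higher and 0 lower (median log2 fold change 1.11, camera adjusted p = 3.2e-04, and adjusted p = 0.270 with an estimated correlation). They were expressed at low levels, Gbp7 at 0.276 ± 0.0559 and 0.920 ± 0.271 CPM (1.73, SE 0.48) and Gbp9 at 0.315 ± 0.244 and 1.53 ± 1.11 CPM (2.23, SE 0.70), and the list was not called with FPKM values (adjusted p = 0.171, in a range of 1.2e-04 to 0.270 over 22 alternatives). Of 35 interferon-stimulated genes, 7 were higher and 1 lower (median 0.16, camera adjusted p = 0.0219, and adjusted p = 0.405 with an estimated correlation). Trim30a was at 0.80 (SE 0.17) and Oasl1 at -0.81 (SE 0.18), and 7 of 22 alternatives lost the call, including those without LPS library 3 and without ferulic acid plus LPS library 2, 3 or both. Of 26 G2 and mitosis genes, 7 were higher and 0 lower (median 0.24, camera adjusted p = 0.00105, and adjusted p = 0.270 with an estimated correlation), Cenpf at 1.00 (SE 0.21) and the mitotic kinesin Kif11 at 0.75 (SE 0.17), and the call was lost without libraries 2 and 3 (adjusted p = 0.187, in a range of 3.9e-06 to 0.270 over 22 alternatives). With the GC trend removed the medians were 0.09 for G2 and mitosis and 0.10 for the interferon-stimulated genes, and the GTPase median was 0.68 without libraries 1 and 4 and 0.55 without libraries 2 and 3 (adjusted p = 3.4e-04 and 0.0173).

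On the lower side, 6 of 20 feedback inhibitors were lower and 0 higher (median -0.29, camera adjusted p = 0.00123), with the transcription factor Atf3 at -0.68 (SE 0.14) and the phosphatase Dusp4 at -0.78 (SE 0.18). Of 24 glycolysis and HIF1 targets, 2 were lower and 0 higher (median -0.32, camera adjusted p = 4.4e-04), Ndrg1 at -0.73 (SE 0.17) and the glucose transporter Slc2a1 at -0.42 (SE 0.12). Of 24 lysosome genes, 5 were lower and 2 higher (median -0.26, camera adjusted p = 0.00848), Gpnmb at -1.16 (SE 0.26) and the proton pump subunit Atp6v0d1 at -0.59 (SE 0.15). Of 22 stress response genes, 0 passed in either direction (median -0.20, camera adjusted p = 0.0142), Ddit4 at -0.46 (SE 0.15) and the amino acid transporter Slc7a5 at -0.43 (SE 0.15), and this call was lost with the GC trend removed (adjusted p = 0.0713) and without libraries 1 and 4 (adjusted p = 0.181), in a range of 0.00659 to 0.270 over 22 alternatives. With the GC trend removed the medians were -0.17 for the feedback inhibitors, -0.17 for glycolysis, -0.12 for lysosome and -0.11 for stress response genes. Without libraries 1 and 4 they were -0.18 for glycolysis, -0.11 for lysosome and -0.09 for stress response genes. All 4 lists had adjusted p = 0.270 with an estimated correlation.

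The other lists described did not pass camera. Of 14 nitric oxide and prostaglandin enzymes Nos2 fell (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.172), and of 22 NRF2 targets Hmox1 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.406, with a median of -0.17 and a mean of 0.09). Of 16 protease and complement genes Plau fell from 18.0 ± 2.67 to 9.86 ± 1.14 CPM (-0.87, SE 0.14, adjusted p = 0.0476), with 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.172). This list was called lower without libraries 1 and 4 (adjusted p = 0.0424), with FPKM values (0.0115) and with fry (0.00748), in a range up to 0.523 over 22 alternatives. No member of the peroxiredoxin, cytokine or chemokine lists passed over all genes. Outside the lists and the rule, and chosen after its values were seen, the cytokine gene Lta fell from 90.1 ± 7.11 to 44.4 ± 10.8 CPM (-1.02, SE 0.18, adjusted p = 0.0476). Its call was lost with the GC trend removed (adjusted p = 0.112). Adjusted over the list alone, 1 peroxiredoxin system gene was higher, Sesn1 (0.53, SE 0.15), and 1 lower, Sesn2 (-0.78, SE 0.18), with camera adjusted p = 0.638. Among cytokines 2 were higher and 1 lower adjusted over the list alone, with Il15 at 0.88 (SE 0.24) and camera adjusted p = 0.753. Among chemokines 0 passed adjusted over the list alone, Ccl9 being at 0.35 (SE 0.16) and Cxcl11 at 0.53 (SE 0.28), with a median of -0.03 and camera adjusted p = 0.780. Without ferulic acid plus LPS libraries 1 and 4 the chemokine list was called lower (median -0.22, adjusted p = 0.0424, in a range of 0.0424 to 0.952 over 22 alternatives), and without libraries 2 and 3 its median was 0.20 (adjusted p = 0.379).

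Further lists had no call with all libraries and gained one in an alternative. Mitochondrially encoded genes (median 0.32, camera adjusted p = 0.303) were called lower without libraries 1 and 4 (-0.34, adjusted p = 0.00618) and with the GC trend removed (-0.17, adjusted p = 0.0283), and higher without libraries 2 and 3 (0.76, adjusted p = 0.00191), in a range of 0.00184 to 0.866 over 22 alternatives. Ribosomal protein genes (median 0.17, camera adjusted p = 0.202) were called higher with the GC trend removed (0.29, adjusted p = 0.00981) and without libraries 2 and 3 (0.40, adjusted p = 0.00209), with a median of -0.13 without libraries 1 and 4, in a range of 0.00184 to 0.8295. Of 23 cholesterol synthesis genes, 4 were higher and 0 lower adjusted over the list alone (median 0.12, camera adjusted p = 0.0996), and the list was called higher in 5 of 22 alternatives, among them those without libraries 1 and 4 (adjusted p = 0.00227) and with the GC trend removed (adjusted p = 0.00936), in a range up to 0.698. Of 22 p53 and apoptosis genes, 3 were lower and 0 higher adjusted over the list alone (median -0.09, camera adjusted p = 0.172), and the list was called lower in 3 of 22, among them the same alternatives (adjusted p = 0.00303 and 0.0300, in a range up to 0.793).

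Whether ferulic acid moved LPS-changed genes back was examined in the same fit. Of the 7372 genes that LPS changed at least 2-fold, 21 changed in the opposite direction with ferulic acid, 14 of them raised by LPS and 7 lowered. Among them were Hmox1, Nos2, Anpep, Ell, Rb1, Lbr and Cul1. Another 6 changed further in the same direction, and all 6 fell in both. Both comparisons share the LPS libraries. Independent lists of these sizes would hold 10.2 opposite and 10.8 same-direction genes, and 50 simulations without a ferulic acid effect gave 0 of either. Those simulations called 0 to 1 ferulic acid genes each (0.06 on average). With almost no calls to sort, they do not show whether shared libraries favour the opposite direction. They also drew genes independently, without structure among libraries, so they cannot exclude such structure as the source of the 21. With the LPS libraries divided between the comparisons, the 6 divisions called 0 to 3 ferulic acid genes in all and gave 0 to 1 opposite and 0 to 2 same-direction genes. The opposite count was 405 with DESeq2, 247 without the low-count filter, 31 with the 10 CPM filter, 1 with library size scaling, 0 without any single control or LPS library, 0, 607, 554 and 2 without ferulic acid plus LPS library 1, 2, 3 and 4, and 1358 without libraries 2 and 3. With the GC trend removed it was 0, where 2 ferulic acid genes were called in all. From the lowest to the highest GC bin, the median log2 fold change ran from -0.43 to 0.45 for LPS against control. For ferulic acid plus LPS against LPS it ran the other way, from 0.36 to -0.23. A GC trend in the shared LPS libraries is therefore not excluded as a source of the 21. Across all tested genes, which are not independent replicates, the 2 log2 fold changes had Pearson r = -0.109 and Spearman rho = -0.0933. The simulations gave r of -0.0866 on average (-0.115 to -0.0577). The covariance was -0.155 against -0.0691 in the simulations, a difference of -0.0856. With the LPS libraries divided between the comparisons, r ran from -0.143 to 0.00909 (median -0.0647). The covariance ran from -0.264 to 0.0167 (median -0.117), so the 6 divisions did not all keep the sign. Without ferulic acid plus LPS library 2, r was 0.00497, and without libraries 2 and 3 it was 0.0425.

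The comparison of ferulic acid plus LPS with control asked what still differed from untreated cells after both treatments. All 17 proinflammatory cytokines were higher than in control (camera adjusted p = 4.8e-10, and adjusted p = 0.0111 with an estimated correlation), and 22 of 26 G2 and mitosis genes were lower (camera adjusted p = 0.150 with an estimated correlation). Csf3 rose by 16.46 (SE 0.45), Lcn2 by 14.63 (SE 0.41), Il1b by 14.16 (SE 0.44), Il1a by 13.86 (SE 0.41), Urah by 13.28 (SE 0.30) and Cxcl2 by 12.49 (SE 0.28), all as log2 fold changes, while Il6 rose 144204-fold in pooled reads (counting interval 39920 to 1190740) and Csf2 31036-fold (8592 to 256277). Kbtbd11 (-6.90, SE 0.31), Cd33 (-5.35, SE 0.20), Cpt1a (-4.99, SE 0.35), the RNA helicase Ddx17 (-4.81, SE 0.28), Selenbp1 (-4.76, SE 0.16), Stard9 (-4.73, SE 0.26), Itga4 (-4.71, SE 0.19) and Trem2 (-4.63, SE 0.19) fell the most by the rule for named genes. Adjusted p was at most 2.1e-09 for each of them. The folds of Urah and Il1a rest on the same 4 and 6 control reads and are again less certain than the SE shows.

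In total 10315 genes changed, 5038 higher and 5277 lower, and 7289 by at least 2-fold. Groups did not overlap in 68.2% of genes, against 2.86% by chance. With library size scaling the split was 2536 higher and 8268 lower, with the median of all genes at -0.97 against -0.07 with TMM, and with limma on log2(FPKM + 1) it was 2233 higher and 6826 lower. Tnf (4.55, SE 0.19), Nos2 (3.76, SE 0.20), Ptgs2 (12.12, SE 0.32), Ccl2 (8.97, SE 0.39), Cxcl10 (6.54, SE 0.21), Prdx1 (2.90, SE 0.29) and Hmox1 (1.58, SE 0.19) were above control. Il10 had 253 reads against 2 in control (ratio 230, counting interval 63.8 to 1903). Tlr4 (-2.25, SE 0.28) and Nlrp3 (-0.73, SE 0.22) were below, with adjusted p of 1.5e-06 and 0.00568. Each named gene kept its call in every alternative run for it.

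All 17 cytokine genes rose, also adjusted over the list alone (camera adjusted p = 4.8e-10, and adjusted p = 0.0111 with an estimated correlation), and 12 of 13 chemokines rose, likewise adjusted over the list alone (camera adjusted p = 1.3e-07, and adjusted p = 0.0670 with an estimated correlation), with Ccl5 at 11.57 (SE 0.33). Of 26 G2 and mitosis genes, 22 fell and 1 rose, with 23 and 1 adjusted over the list alone (camera adjusted p = 1.6e-05, and adjusted p = 0.150 with an estimated correlation), Mki67 by a log2 fold change of -3.42 (SE 0.17) and Cenpf by -3.13 (SE 0.21). Of 19 replication-dependent histones, 10 rose and 0 fell, likewise adjusted over the list alone (camera adjusted p = 0.0329, and adjusted p = 0.319 with an estimated correlation), with H1f2 at 4.31 (SE 0.15) and H2bc4 at 4.04 (SE 0.18). The histone call was lost in 6 of 22 alternatives, among them those without control library 3 and without ferulic acid plus LPS library 4, and with the length trend removed the median went from 1.17 to 0.12 (adjusted p = 0.903, in a range of 5.0e-06 to 0.903). Camera called 17 of 35 lists (14 higher, 3 lower), and 2 with an estimated correlation.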

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

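No test in this part was planned, and the values below were picked out by their distance from the other 3 libraries of a group. In 294 groups of 4 libraries, covering the named genes and the library measures, 21 held 1 library whose gap to the nearest other exceeded the 95% critical value for 4 samples, where chance alone gives 1 in 20, or 14.7. Control library 2 held 5 of them, LPS library 4 held 3, and LPS library 2 and ferulic acid plus LPS library 1 held 0.

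In several cases 2 reads in 1 control library met 0 in the other 3: Csf2 in control library 1 (0.0344 CPM), Ifnb1 in library 4 (0.0377 CPM), Il10 and Mmp13 in library 2 (0.0373 CPM each) and Il6 in library 3 (0.0275 CPM). Among the other control values, Tnf (17.3 CPM, the others at most 12.5), Cd40 (6.06 CPM, at most 4.09) and H1f2 (19.2 CPM, at most 17.2) were high in library 2. Pole was high in library 1 (49.7 CPM, at most 44.5) and Mat2a low in library 3 (81.1 CPM, at least 86.5).

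Among the LPS libraries, Bcl3 (117 CPM, the others at most 82.7) and Tap1 (193 CPM, at most 169) were high in library 1. Rrm1 (56.9 CPM, at most 41.3) and Zbp1 (197 CPM, at most 180) were high in library 3. Hmox1 (931 CPM, at most 657), Plau (22.02 CPM, at most 17.2) and Sesn2 (38.1 CPM, at most 28.3) were high in library 4. In the ferulic acid plus LPS group, Itga4 was high in library 2 (62.1 CPM, at most 43.6), Urah in library 3 (226 CPM, at most 190) and Mmp13 in library 4 (121 CPM, at most 81.0), and Wdr81 was low in library 4 (5.80 CPM, at least 7.98).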

How the results depend on the processing

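The alternatives for GC and length trends, library weights, the omission of ferulic acid plus LPS libraries 1 and 4 or 2 and 3, and lists with libraries left out or library size scaling were chosen after seeing the data. For LPS against control and ferulic acid plus LPS against control, the counts of genes stayed within 1.5 times under every alternative (9945 to 10910 and 9844 to 10777 with 1 library left out), and the 53 and 31 named genes kept their calls in the alternatives run for them. For ferulic acid plus LPS against LPS the 40 calls became 16 with a 2-fold minimum, 2 with library size scaling, 1041 with DESeq2, 719 with no filter, 71 with 10 CPM, 0 with only the 2 groups, 5 and 3 with FPKM plus 1 and plus 0.1, 0 to 2670 with 1 library left out, 2 with the GC trend removed, 92 with the length trend removed, 3400 with library weights, 7 without libraries 1 and 4 and 5664 without libraries 2 and 3. In the same order, the 21 opposite-direction genes became 1 with library size scaling, 405 with DESeq2, 247 with no filter, 4 and 2 with FPKM, 0 to 607 with 1 library left out, 0 with the GC trend removed, 42 with the length trend removed, 830 with weights, 4 without libraries 1 and 4 and 1358 without libraries 2 and 3. The correlation of fold changes was -0.256 with no filter, -0.0263 with weights, 0.0425 without libraries 2 and 3 and -0.210 to 0.00497 with 1 library left out, the last without ferulic acid plus LPS library 2. Leaving out ferulic acid plus LPS library 2 or 3 raised the calls to 2670 and 1415, and the cause was not tested for any of these changes.

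Called lists fell from 17 to 5 in LPS against control, from 7 to 0 in ferulic acid plus LPS against LPS and from 17 to 2 in ferulic acid plus LPS against control with an estimated correlation. They rose to 31, 15 and 27 with fry, which tests another question, and to 11 for ferulic acid plus LPS against LPS without libraries 1 and 4. With 1 library left out they numbered 16 to 18, 6 to 8 and 16 to 17. The replicate number as a block gave 0 calls for ferulic acid plus LPS against LPS (2450 at an unadjusted p under 0.05) and 0 opposite-direction genes. It gave 10041 genes for LPS against control and 9935 for ferulic acid plus LPS against control. The named genes of both kept their calls, and no described list changed its call in any comparison. Same-numbered libraries correlated at -0.203 to 0.0838, and 0 of 12 correlated best with their own number. These correlations thus showed no pairing, but with 4 libraries per group they cannot exclude one. Library 3 had the largest total of each group, with 48446195 counts in control, 47276784 in LPS and 49961581 in ferulic acid plus LPS. A batch shared by libraries of the same number therefore stays open. At the real depths and with 4 libraries per group, 26.9% of simulated 1.5-fold changes were recovered, and what depth alone limits was not tested.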

Other observations

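In LPS against control, several lists not described above moved in both directions. Camera called the NADPH oxidase and redox enzymes (9 of 12 higher, 1 lower, adjusted p = 0.0298, and adjusted p = 0.255 with an estimated correlation) and oxidative phosphorylation (21 of 31 higher, 4 lower, adjusted p = 0.0124, and adjusted p = 0.297 with an estimated correlation). Their medians flipped from 0.65 to -0.25 and from 0.74 to -0.16 with library size scaling, and the second call was lost with the length trend removed (adjusted p = 0.0736). With that trend removed, glycolysis (adjusted p = 0.0485) and mitochondrially encoded genes (median -1.53, adjusted p = 0.0186) were called. Lists without a call were NRF2 targets (12 higher and 8 lower of 22), glycolysis (12 and 6 of 24), lysosome (13 and 7 of 24), MHC class II (5 and 3 of 11) and replication-dependent histones (5 and 0 of 19), and their medians flipped with library size scaling too. Inflammasome genes (5 higher and 9 lower of 15), other pattern receptors (6 and 9 of 16), alternative activation (4 and 7 of 12), cholesterol efflux (5 and 9 of 15), guanylate-binding GTPases (3 and 3 of 9) and mitochondrially encoded genes (3 and 7 of 15) were not called either.

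Markers of other cell types gave no call in LPS against control: osteoclast (4 higher and 5 lower of 10), dendritic cell (4 and 1 of 6), neutrophil and monocyte granule (1 and 1 of 3), fibroblast (2 and 1 of 4) and B cell markers (2 and 1 of 4, with a median of 0.67 that flipped to -0.23 with library size scaling). Of the T and NK markers 1 was tested and rose, and of the epithelial markers 0 were tested. With ferulic acid plus LPS against LPS, 0 members of these lists changed over all genes and camera called none of those tested. Adjusted over the list alone, 1 osteoclast marker was higher and 3 lower (median -0.41, camera adjusted p = 0.0996, fry adjusted p = 0.00748), 2 of 4 fibroblast markers were higher (median 1.12, camera adjusted p = 0.0996, fry adjusted p = 0.0226, and a median of 0.66 without libraries 1 and 4), 1 granule marker was lower (fry adjusted p = 0.104), and 0 dendritic or B cell markers passed. The 1 T and NK marker tested was lower in that sense too (-0.33), where nothing was adjusted for. Outside the rule, and chosen after its values were seen, the DNA repair gene Ercc1 had a log2 fold change of 7.32 with LPS (SE 0.21) and of -0.82 with ferulic acid added (SE 0.16, adjusted p = 0.0476).

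Of the tests that follow, those on GC content for the 40 genes and on exchanged labels were chosen after the result was seen, and that on the smallest p over all lists after the list results but before its own value was known. Trend removal and the omission of libraries 1 and 4 or 2 and 3 are alternatives added after seeing the data. The first pattern is the 40 genes called between ferulic acid plus LPS and LPS. With the GC trend removed they kept a median share of 0.761 of their log2 fold change (quartiles 0.696 and 0.846), and the rest of that change went with GC. The trend itself ran from a median of 0.36 in the lowest GC bin to -0.23 in the highest, beside a median absolute change of 0.92 in these genes. Most of so large a change would be kept whatever its source, so this share does not decide whether GC content was the cause. The calls of 38 ended (median absolute log2 fold change 0.92, SE 0.17, before and 0.73, SE 0.14, after, adjusted p of 0.0522 to 0.168), as p rose for 31 of the 40 (median 7.5e-05 before and 1.8e-04 after), and with their earlier p set among the corrected genes all 40 would be called. Of the 35 splits of the 8 libraries, 4 gave as many calls as the real one, the highest other 1473 against 40, so chance is not excluded and the samples hold another structure. That highest split exchanges the libraries numbered 2. The splits with 1241 and 977 calls, like it, set ferulic acid plus LPS library 2 together with LPS libraries 3 and 4. The one with 1241 exchanges that library with LPS library 1, so the calls do not single out a pair. A mislabelled sample may or may not be behind them.

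The second pattern is that fewer genes were detected after LPS: 18893 ± 266 in control, 16203 ± 501 in LPS and 16007 ± 642 in ferulic acid plus LPS libraries (exact permutation p = 0.0286 for either against control, the smallest possible, 0.0771 adjusted over 27 tests). After thinning to the lowest total, the lowest control library still exceeded the highest LPS-treated one by 1952 genes, which argues against depth. Without the 200 most abundant genes and thinned the gap was 1677, which argues against a few genes taking the counts, and at a minimum of 10 reads it was 699 against 1799 as deposited. Ribosomal RNA, measured by a single gene row and so incompletely, took 4.70% ± 0.818 of the counts in control and 4.85% ± 1.25 in LPS libraries (exact permutation p adjusted over the same tests 0.926). Mitochondrial genes took 4.14% ± 0.258 and 3.71% ± 0.484 (0.360). The length trend moved with LPS, so RNA quality stays open beside a narrower expressed repertoire, which may be followed up as a hypothesis.

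The third pattern is the guanylate-binding and immunity-related GTPase list, higher with ferulic acid plus LPS by a median of 1.11. The median was 1.05 with the GC trend removed, and 0.68 without ferulic acid plus LPS libraries 1 and 4, with camera adjusted p of 5.3e-04 and 3.4e-04, which argues against either as the whole cause, although the second took part of the size, and so did libraries 2 and 3 (0.55 without them, adjusted p = 0.0173). Of the 35 splits 1, the real one, gave a median this far from 0 (the highest other 0.77), but 1 of 35 is the smallest share these splits can give, and it makes no allowance for this list having the smallest camera p of 35. With that choice repeated in each split, 12 of 35 gave as small a p, the smallest other being 3.1e-09 against 9.1e-06, so chance is not excluded. Low counts and correlation between these genes stay open too (adjusted p = 0.270 with an estimated correlation), and an effect of ferulic acid may be followed up only as a hypothesis.

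The same splits were run for the other results. For LPS against control 1 of 35 gave as many calls (10384, the highest other 0), and for ferulic acid plus LPS against control 1 of 35 (10315, the highest other 1), which argues against chance for both. For ferulic acid plus LPS against LPS 1 of 35 splits called as many lists (7, the highest other 5), the smallest share these splits can give. The margin is narrow and no allowance is made for the number of split tests run, so chance is not excluded for the count. It is not excluded for the lists themselves either, since 12 of 35 splits matched the smallest p and 0 lists were called with an estimated correlation. For LPS against control (5 of 35, 17 lists and the highest other 18) and ferulic acid plus LPS against control (4 of 35, 17 and 18) the count of lists decides nothing, because splits that move 1 library still called 14 to 18 and 13 to 18 lists with at most 0 and 1 genes called. Chance is not excluded for the 21 opposite-direction genes (7 of 70 splits, the highest other 813) or for r = -0.109 (41 of 70, the lowest other -0.396).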
